A study of Mus musculus with 12 samples.

How the data were processed

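Bulk RNA sequencing of orthotopic mouse pancreatic tumours was read from 12 libraries in 4 groups of 3: vehicle, EC359, gemcitabine and EC359 with gemcitabine. The labels give poly(A) selection, or ribosomal RNA removal as an alternative, before stranded library preparation, and do not say which was used for which library. Per the submitters' processing notes, FastQC, cutadapt, HISAT2 and StringTie were run against the GRCm38 mouse genome, with no versions given. The deposited table holds FPKM, that is fragments per kilobase of transcript and per 1000000 mapped fragments, computed by the authors for each gene and library. It lists 12863 protein-coding genes, and the highest of the 4 group means is at least 0.5 FPKM for each of them, so genes low in all groups were removed before deposition. Of 20 T-cell markers fixed for this work 3 are in the table, and of 20 B-cell and plasma cell markers 5. A marker can be absent by its gene type as well as its level, so the absences do not measure these cells. The annotation release is not stated. With its version suffix, the Ensembl identifier of 11273 genes matched mouse GENCODE release M21, with the same coordinates, and 12854 matched without the suffix.

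Read totals are not in the table, so the depth of each library is unknown and no counting interval is given. FPKM sums over the listed genes ran from 281303 to 325823 per library. Because FPKM divide by each library's total, a rise of a few abundant transcripts lowers the values of all others. Genes whose reads can be placed on transcripts of different length can also change in FPKM without a change in read number.

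Genes with a mean of at least 0.5 FPKM over the 12 libraries were tested, 12352 in number. Values were taken as log2(FPKM + 1). The added 1 understates the fold change of genes with low FPKM. Group means were fitted over all 12 libraries with limma 3.58.1 in R 4.3.3, using moderated statistics with a mean-variance trend, and p-values were two-sided and adjusted by Benjamini-Hochberg over all tested genes. A gene was called changed at an adjusted p under 0.05. Errors of log2 fold changes are standard errors from that fit, and errors of FPKM are SD over 3 libraries. Comparisons were each treated group against vehicle, the combination against each single drug, and the interaction, which is the effect of EC359 with gemcitabine minus its effect without. The p-values measure the spread between these libraries, which the labels do not say come from separate animals. A comparison of 2 groups of 3 libraries allows no exact permutation p under 0.1.

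Before the data were examined, 42 gene lists for pathways, cell types and RNA quality were fixed, and 38 of them had at least 5 measured members and were tested. Limma's camera compared each list with all other genes at a preset correlation between genes of 0.01, and was repeated with the correlation estimated for each list. Limma's fry, also fixed in advance, tested each list for change on its own, without comparing it with other genes. Adjusted p-values of lists were corrected over the 38 lists in a comparison. Counts of changed members are given for the adjustment over all genes tested and for that "adjusted over the list alone". The comparisons, the filter, the tests and the rule for naming genes were also fixed at that point. The rule took, in each direction, up to 10 genes with the largest change among called genes with at least 5 FPKM in one group and no overlap between the groups (5 in the comparison with EC359 and in the interaction). Where fewer than 5 genes qualified, it took the 5 with the smallest unadjusted p, as values only. It also took up to 4 members with the smallest p from each list, and a fixed set of genes of the LIF pathway, proliferation, gemcitabine metabolism, fibroblasts and pancreas. Unnamed predicted genes were skipped.

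The fit was tested on simulated data with 50 genes changed at each of several fold sizes: 16% were recovered at 1.5-fold, 82% at 2-fold and 98% at 4-fold, with 9 false calls. The simulated noise was independent between genes, so shifts shared by many genes of a library were absent. Changes were added to log2(FPKM + 1), so the loss of fold at low FPKM was absent too. Alternatives fixed in advance were a pseudocount of 0.1, no filter, a filter at 2 FPKM, trimmed-mean scaling factors (computed directly on FPKM), quantile normalization, rescaling to a sum of 1000000, no trend, array weights, a fit of only the 2 groups compared, the replicate number as a block, and each library left out in turn. Tools for read counts were not applicable. A covariate for the acinar score, a covariate for the Y-linked gene Eif2s3y, removal of the acinar list before rescaling, removal of EC359 libraries 1 and 3, and comparisons that pool both arms of each drug were added after seeing the data. The closing section gives their effect.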

Results

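RNA was sequenced from pancreatic tumours of C57BL/6 mice. The tumours were grown from KCT3266 cells, a mouse pancreatic ductal adenocarcinoma line from a Kras- and Trp53-mutant tumour, implanted into the pancreas together with mouse cancer-associated fibroblasts (CAFs) in equal numbers. Treatment began once tumours could be felt, at about day 10. The 4 groups of 3 libraries received vehicle, EC359 at 5 mg/kg, gemcitabine at 25 mg/kg, or both drugs, hereafter the combination, whose doses are not stated separately. EC359 inhibits LIFR, the receptor of the cytokine LIF, and gemcitabine is a nucleoside analogue used as chemotherapy. The series asks whether blocking the LIF and LIFR axis of CAFs improves chemotherapy. Mice of both sexes were used, and the sex of each animal is not labelled.

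Expression was given as FPKM for 12863 protein-coding genes, without read totals, so depth is unknown. FPKM sums were 281303 to 325823 per library. The first principal component held 43.3% of the variance and placed the 6 libraries from mice given gemcitabine at 9.1 to 32.2 and the other 6 at -38.6 to -14. Within groups, Pearson's r across genes was 0.951 to 0.983; genes are not independent replicates. Acinar transcripts, the digestive enzymes of the normal exocrine pancreas, made up 4.96% ± 2.26 of the FPKM sum with vehicle, 4.32% ± 6 with EC359, 12.1% ± 1.11 with gemcitabine and 9.41% ± 3.58 with the combination (SD, n = 3). EC359 library 3 held 0.2% and EC359 library 1 was led by the haemoglobin gene Hbb-bs.

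Gemcitabine was compared with vehicle to ask what the chemotherapy alone changed. Csf2, Agr2 and Prss3 had the largest rises among the genes named by rule. Csf2, which encodes GM-CSF (ENSMUSG00000018916.5, GRCm38 chromosome 11, 54247271 to 54249667), rose by a log2 fold change of 3.36 ± 0.28, from 3.54 ± 0.61 to 47.3 ± 16 FPKM (SD, n = 3; limma adjusted p = 8.20e-04). The eosinophil chemoattractants Ccl24 (2.18 ± 0.35) and Ccl11 (2.16 ± 0.38) and the inflammatory cytokine Il1b (1.99 ± 0.42) also rose. Other rises were in Agr2, a disulfide isomerase of secretory epithelium (3.30 ± 0.67), Pigr, the polymeric immunoglobulin receptor (2.34 ± 0.54), and the trypsinogen Prss3 (3.25 ± 0.77). The largest falls among them were in Apoa1, the main HDL apolipoprotein (-2.72 ± 0.63), the sulfotransferase Sult1d1 (-2.61 ± 0.65), the thyroxine carrier Ttr (-2.19 ± 0.38), the trefoil peptide Tff3 (-2.19 ± 0.56) and the retinaldehyde dehydrogenase Aldh1a1 (-2.0 ± 0.36). The remaining genes named by rule were Wfdc18, Gzmc and Penk, which rose, and Akr1b7, Cyp2s1, Ets1, Ephx2 and Entpd2, which fell. In total 1592 genes changed, 648 up and 944 down, and 266 changed at least 2-fold.

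Cell division genes rose together. Of 27 measured mitosis genes, 24 rose and none fell (26 rose adjusted over the list alone), with a median log2 fold change of 0.78. Examples were Ube2c, a ubiquitin-conjugating enzyme of anaphase (1.2 ± 0.14), the survivin gene Birc5 (0.95 ± 0.13), the kinetochore gene Cenpf (0.93 ± 0.12) and cyclin Ccnb2 (0.84 ± 0.11). The camera adjusted p for mitosis was 3.21e-24, and the adjusted p = 0.137 with an estimated correlation. The proliferation marker Mki67 rose by 0.76 ± 0.15. DNA replication genes had a median of 0.21 and a camera adjusted p of 0.00109, but 0 of 31 rose or fell in limma, also adjusted over the list alone (adjusted p = 0.539 with an estimated correlation). Rrm2, the small subunit of ribonucleotide reductase, stood at -0.15 ± 0.22, and Dck, the kinase that activates gemcitabine, at 0.19 ± 0.15. Among 18 genes of gemcitabine transport and metabolism, the exporter Abcc5 (-0.80 ± 0.20) and the nucleotidase Nt5c3 (-0.50 ± 0.13) fell, both also adjusted over the list alone. Of 25 p53 target genes, Gdf15 (0.51 ± 0.14) and Psrc1 (0.53 ± 0.14) rose, neither of them adjusted over the list alone, while Cdkn1a stood at 0.03 ± 0.44.

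Fibroblast genes rose in 3 lists. Inflammatory CAF genes had a median of 0.91, and 9 of 18 rose (14 adjusted over the list alone), including the chemokines Cxcl1 (1.95 ± 0.23) and Ccl7 (1.94 ± 0.39), the hyaluronan synthase Has2 (1.65 ± 0.34) and Il6 (1.48 ± 0.30). Myofibroblastic CAF genes had a median of 0.70, and 9 of 16 rose (9 adjusted over the list alone). The matrix glycoprotein Tnc rose by 1.83 ± 0.25, the actin-binding Tagln by 1.29 ± 0.24 and Acta2, smooth muscle actin, by 1.18 ± 0.26, from 68.5 ± 15.6 to 154 ± 14.6 FPKM (SD, n = 3). Of 22 extracellular matrix and pan-fibroblast genes, 5 rose (15 adjusted over the list alone), among them Pdpn (1.35 ± 0.30), Bgn (0.88 ± 0.20) and Mfap5 (0.68 ± 0.12), while Col1a1 stood at 0.55 ± 0.23. The camera adjusted p was 8.96e-10 for inflammatory CAF, 1.98e-07 for myofibroblastic CAF and 4.37e-09 for matrix genes. With an estimated correlation the adjusted p = 0.137, adjusted p = 0.137 and adjusted p = 0.485, in that order. Of 18 epithelial-mesenchymal transition genes, 8 rose and Cdh2 (-0.72 ± 0.15) fell (10 rose and 2 fell adjusted over the list alone), with Snai1 (0.87 ± 0.21) and Zeb2 (0.57 ± 0.13) among the rises and a camera adjusted p of 1.23e-04 (adjusted p = 0.137 with an estimated correlation). Acinar genes had a median of 1.49 in the same libraries, and 2 of 30 rose (1 adjusted over the list alone), with Prss2 at 1.66 ± 1.07. Their camera adjusted p was 3.47e-05, and adjusted p = 0.539 with an estimated correlation. Islet genes had a median of 1.03 with 0 of 10 called (camera adjusted p = 0.00589, and adjusted p = 0.539 with an estimated correlation). The islet call was lost without vehicle 2 (median 0.47, camera adjusted p = 0.119).

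**Figure D1:**
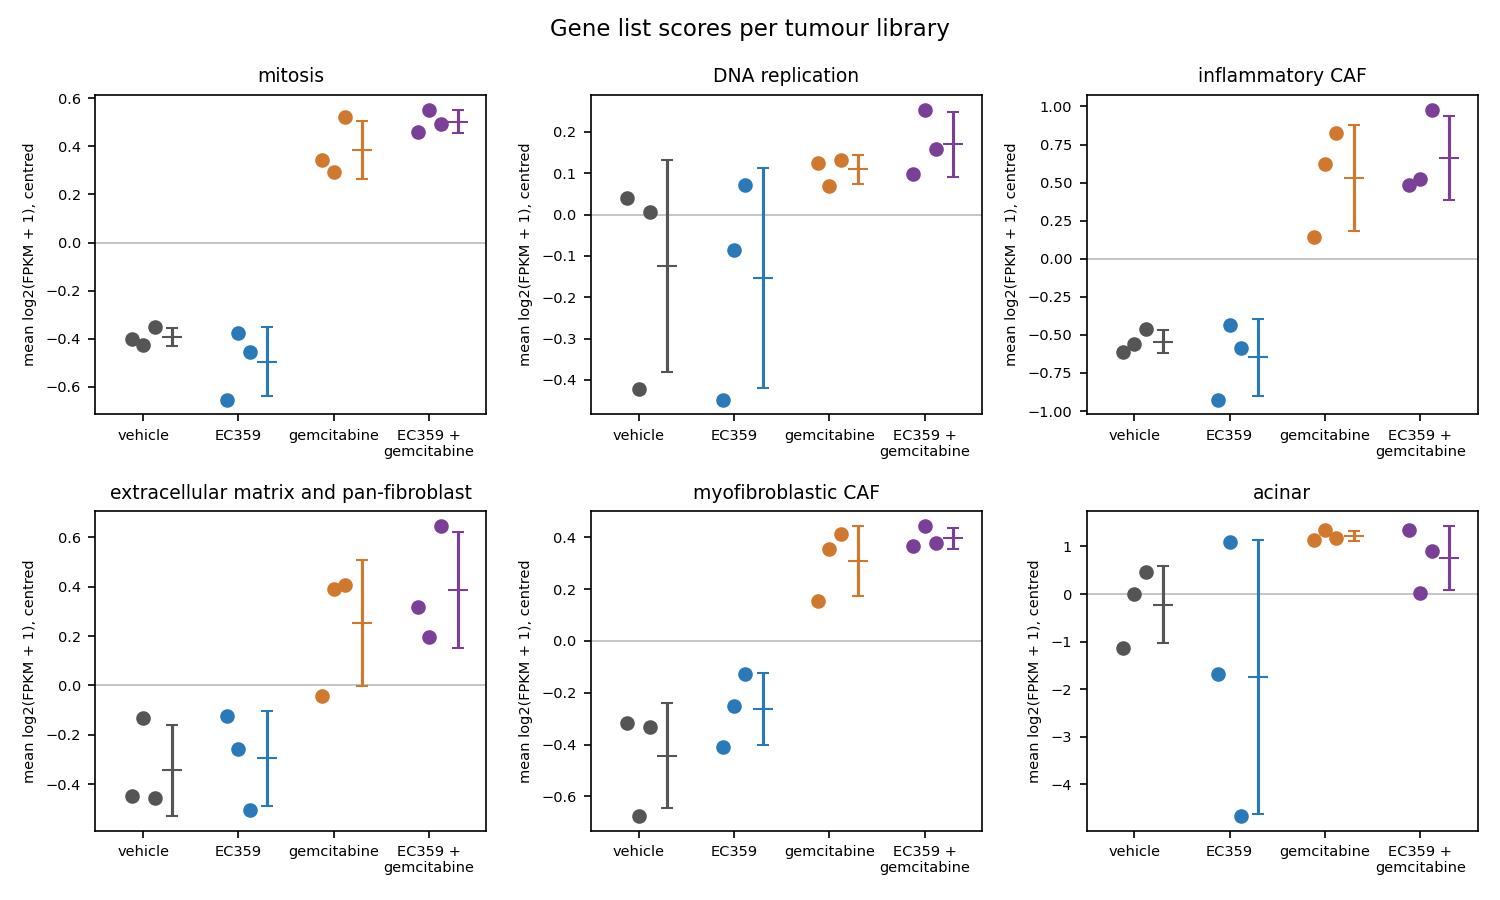
Mean centred log2(FPKM + 1) of 6 fixed gene lists per library; points are libraries (n = 3 per group) and the bar is the mean ± SD. Mitosis scores were 0.29 to 0.55 in the 6 libraries given gemcitabine and -0.66 to -0.35 in the other 6, while acinar scores spread from -4.67 to 1.09 with EC359.

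Macrophage, neutrophil and type I interferon lists were higher with gemcitabine and had few called members, while other immune lists did not all pass. Macrophage genes had a median of 0.54 with 3 of 20 risen (4 adjusted over the list alone), namely the folate receptor Folr2 (0.88 ± 0.16), the Fc receptor Fcgr1 (1.05 ± 0.27) and lysozyme Lyz2 (1.05 ± 0.31). Neutrophil genes had a median of 0.95 with 4 of 17 risen (5 adjusted over the list alone), including Trem1 (1.03 ± 0.23). Type I interferon genes had a median of 0.32 with 3 of 30 risen (3 adjusted over the list alone): Ifi27l2a (1.47 ± 0.31), Trim30a (1.00 ± 0.24) and Oas1a (0.83 ± 0.22). The camera adjusted p was 3.59e-05, 3.97e-05 and 3.47e-05 for macrophage, neutrophil and interferon genes, and with an estimated correlation the adjusted p = 0.485, adjusted p = 0.485 and adjusted p = 0.539. MHC class II genes had a median of 0.60 with 1 of 7 risen (2 adjusted over the list alone), and dendritic cell genes 0.36 with 2 of 7 (2). Their camera adjusted p was 0.0145 and 0.0177, and adjusted p = 0.539 for both with an estimated correlation. Both calls were lost without vehicle 3 (medians 0.37 and 0.25) or gemcitabine 2 (medians 0.33 and 0.21). Camera did not call interferon gamma and MHC class I (adjusted p = 0.23), B and plasma cell (0.139), cytotoxic and NK cell (0.139) or immune checkpoint genes (0.174). In the LIF-IL6 family, Crlf1 (1.18 ± 0.18), Il11 (1.86 ± 0.35) and Il6 rose and the STAT inhibitor Pias3 (-0.67 ± 0.19) fell among 18 genes, the same numbers adjusted over the list alone, and the list had a camera adjusted p of 0.0953. Lif stood at 0.33 ± 0.24, Lifr at 0.34 ± 0.45, Il6st at 0.13 ± 0.26, Stat3 at 0.02 ± 0.13 and Socs3 at 0.42 ± 0.18, none of them called. Of 22 STAT3 targets, Timp1 (1.66 ± 0.25) and Hif1a (0.68 ± 0.16) rose, both also adjusted over the list alone (camera adjusted p = 0.00815; adjusted p = 0.485 with an estimated correlation). Intestinal genes were lower, with Apoa1 and Vil1 (-0.94 ± 0.14) fallen of 6 (4 adjusted over the list alone; camera adjusted p = 0.0145; adjusted p = 0.485 with an estimated correlation). Ductal and stem cell factor genes had medians of -0.23 and -0.20 while camera, which weighs all members, pointed upward and did not pass (adjusted p = 0.661 and 0.861).

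Without vehicle 1, vehicle 2, gemcitabine 2 or gemcitabine 3, 274, 661, 165 and 111 genes changed in place of 1592, while 848 changed in a fit of these 2 groups alone, 1050 with replicate number as a block and 3518 with array weights. Of 93 named calls, 14 stood without each library in turn: those of Csf2, Ccl24, Cxcl1, Tnc, Timp1, Crlf1, Ube2c, Birc5, Cenpf, Ccnb2, Mfap5, Vil1, Prom1 and Ets1. With the acinar score as a covariate 790 genes changed, and with the Y-linked Eif2s3y as a covariate 693; the lost calls kept 94.4% and 97.6% of their median fold change, and their median SE rose from 0.155 to 0.167 and from 0.153 to 0.175. The share of changed genes that rose was 40.7%, and 22.6% after each library was rescaled to the same sum. The DNA replication call rested on vehicle 2 (adjusted p = 0.1 without it).

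The combination was compared with vehicle to ask what both drugs together changed. The same cytokine led the rises: Csf2 rose by 3.64 ± 0.28 to 55.2 ± 3.8 FPKM (SD, n = 3; limma adjusted p = 3.53e-04). It was followed by Prss3 (3.41 ± 0.77), Ccl24 (2.90 ± 0.35), Il11, an IL6-family cytokine (2.45 ± 0.35), Retnla, a product of alternatively activated macrophages (2.38 ± 0.46), and the chemokines Ccl11 (2.35 ± 0.38), Ccl17 (2.32 ± 0.42) and Ccl7 (2.28 ± 0.39). The largest falls were in Sult1d1 (-3.20 ± 0.65), Apoa1 (-2.79 ± 0.63), Tff3 (-2.49 ± 0.56), Ttr (-2.42 ± 0.38) and the retinol-binding Rbp2 (-2.25 ± 0.39). Enzymes of xenobiotic and retinoid metabolism were among the other falls: Akr1b7 (-2.20 ± 0.60), Aldh1a1 (-2.14 ± 0.36), the glucuronosyltransferase Ugt2b35 (-2.14 ± 0.35), the epoxide hydrolase Ephx2 (-2.04 ± 0.42) and the alcohol dehydrogenase Adh7 (-1.92 ± 0.33). Wfdc18 and Gif also rose. In total 1552 genes changed, 893 up and 659 down, and 345 at least 2-fold.

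Mitosis genes rose in 25 of 27 cases (27 adjusted over the list alone), with a median of 0.92, led by Cdc20, an activator of the anaphase-promoting complex (1.09 ± 0.12), Birc5 (1.06 ± 0.13) and Tpx2 (0.97 ± 0.11). Their camera adjusted p was 4.74e-25, and the adjusted p = 0.144 with an estimated correlation. Inflammatory CAF genes rose in 12 of 18 cases (16 adjusted over the list alone; median 1.1; camera adjusted p = 4.65e-10), including Cxcl1 (1.92 ± 0.23), Col14a1 (1.23 ± 0.21) and Pi16 (1.01 ± 0.16). Extracellular matrix and pan-fibroblast genes rose in 14 of 22 cases (19 adjusted over the list alone; median 0.71; camera adjusted p = 4.65e-10), including Col1a1 (0.95 ± 0.23), Col1a2 (0.90 ± 0.18) and Col3a1 (0.96 ± 0.21). Myofibroblastic CAF genes rose in 10 of 16 cases (12 adjusted over the list alone; median 0.85; camera adjusted p = 9.67e-08), including Tnc (1.93 ± 0.25), the activin subunit Inhba (1.76 ± 0.30) and Acta2 (1.24 ± 0.26). With an estimated correlation, these 3 fibroblast lists had adjusted p = 0.171, adjusted p = 0.299 and adjusted p = 0.162. The acinar list had a median of 0.93 in the same libraries, with 1 of 30 genes risen, Prss1 (1 adjusted over the list alone). Its camera adjusted p was 0.00946, and adjusted p = 0.683 with an estimated correlation. Islet genes had a median of 0.82 with 0 of 10 called (camera adjusted p = 0.0469, and adjusted p = 0.639 with an estimated correlation). The islet call was lost without vehicle 2 (median 0.15, camera adjusted p = 0.588).

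MHC class II and type I interferon genes were higher as well. Interferon gamma and MHC class I genes had a median of 0.31 with 1 of 23 risen (1 adjusted over the list alone). Their camera adjusted p was 0.0153, and adjusted p = 0.514 with an estimated correlation. That call was lost without combination 1 (median 0.22, camera adjusted p = 0.219) and with Eif2s3y as a covariate (median 0.11, camera adjusted p = 0.115). MHC class II genes had a median of 1.34, and H2-DMa (1.4 ± 0.29), H2-DMb1 (0.98 ± 0.28) and H2-DMb2 (0.98 ± 0.21) rose of 7 (7 adjusted over the list alone; camera adjusted p = 2.93e-04; adjusted p = 0.374 with an estimated correlation). Type I interferon genes rose in 9 of 30 cases (13 adjusted over the list alone), led by Ifi27l2a (1.78 ± 0.31), Trim30a (1.43 ± 0.24) and Oas1a (1.25 ± 0.22), with a camera adjusted p of 2.68e-07 (adjusted p = 0.374 with an estimated correlation). Macrophage genes rose in 5 of 20 cases (12 adjusted over the list alone), including Folr2 (1.15 ± 0.16), Fcgr1 (1.30 ± 0.27) and Adgre1, the F4/80 antigen (0.92 ± 0.24), with a camera adjusted p of 6.11e-07 (adjusted p = 0.306 with an estimated correlation). Of 7 dendritic cell genes 4 rose (5 adjusted over the list alone), Ccl17, Itgax (1.75 ± 0.31), Ccl22 (1.05 ± 0.27) and Irf8 (0.43 ± 0.13), with a camera adjusted p of 4.91e-04 (adjusted p = 0.343 with an estimated correlation). Of 25 p53 targets, 5 rose (7 adjusted over the list alone), including Gdf15 (0.99 ± 0.14), Plk3 (0.58 ± 0.14), Mdm2 (0.52 ± 0.13) and Eda2r (0.51 ± 0.14), with a camera adjusted p of 0.00946 (adjusted p = 0.299 with an estimated correlation). Of 22 STAT3 targets, 6 rose (10 adjusted over the list alone), including Timp1 (1.69 ± 0.25), Lcn2 (1.88 ± 0.53) and Hif1a (0.78 ± 0.16), with a camera adjusted p of 4.91e-04 (adjusted p = 0.231 with an estimated correlation). Of 18 LIF-IL6 family genes, 4 rose and 1 fell (5 rose and 1 fell adjusted over the list alone), with a median of 0.149 and a camera adjusted p of 0.0469 (adjusted p = 0.435 with an estimated correlation). That call was lost without any 1 of 7 libraries (medians 0.093 to 0.189) and with the acinar (median 0.12; adjusted p = 0.125) or Eif2s3y covariate (median 0.116; adjusted p = 0.105). Lif stood at 0.67 ± 0.24 (limma adjusted p = 0.0885), Socs3 at 0.52 ± 0.18 and Lifr at 0.09 ± 0.45, and none was called.

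Without vehicle 1, vehicle 2, combination 1, combination 2 or combination 3, 720, 858, 728, 953 and 632 genes changed in place of 1552, while 2427 changed with array weights and 598 with Eif2s3y as a covariate, under which the lost calls kept 94.1% of their median fold change and their median SE rose from 0.16 to 0.186. Of 107 named calls, 57 stood without each library in turn, those of Csf2, Il11, Ccl24, Sult1d1, Ttr, Cdc20 and Tnc among them and those of Prss3, Apoa1, Tff3, Akr1b7, Col1a1 and Col3a1 not. The Y-linked Eif2s3y itself was 0.185 ± 0.19 FPKM in the combination and 1.5 ± 1.3 with vehicle (SD, n = 3). Lists fixed for RNA quality moved in the same comparison. Mitochondrially encoded genes had a median of -0.46 (camera adjusted p = 0.00497, and adjusted p = 0.483 with an estimated correlation). Ribosomal protein genes had -0.11 (camera adjusted p = 0.0112, and adjusted p = 0.639 with an estimated correlation). Replication-dependent histones had 0.35 (camera adjusted p = 0.0162, and adjusted p = 0.435 with an estimated correlation). The non-coding RNAs of that list were not measured, as only protein-coding genes are listed. The mitochondrial call was lost without vehicle 3 (adjusted p = 0.122) or combination 3 (adjusted p = 0.055), the histone call without the same libraries (adjusted p = 0.0515 and 0.129), and the ribosomal call without vehicle 2 (adjusted p = 0.0504). The acinar call was lost without vehicle 1 (adjusted p = 0.195) and without combination 1 (adjusted p = 0.101).

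**Figure D2:**
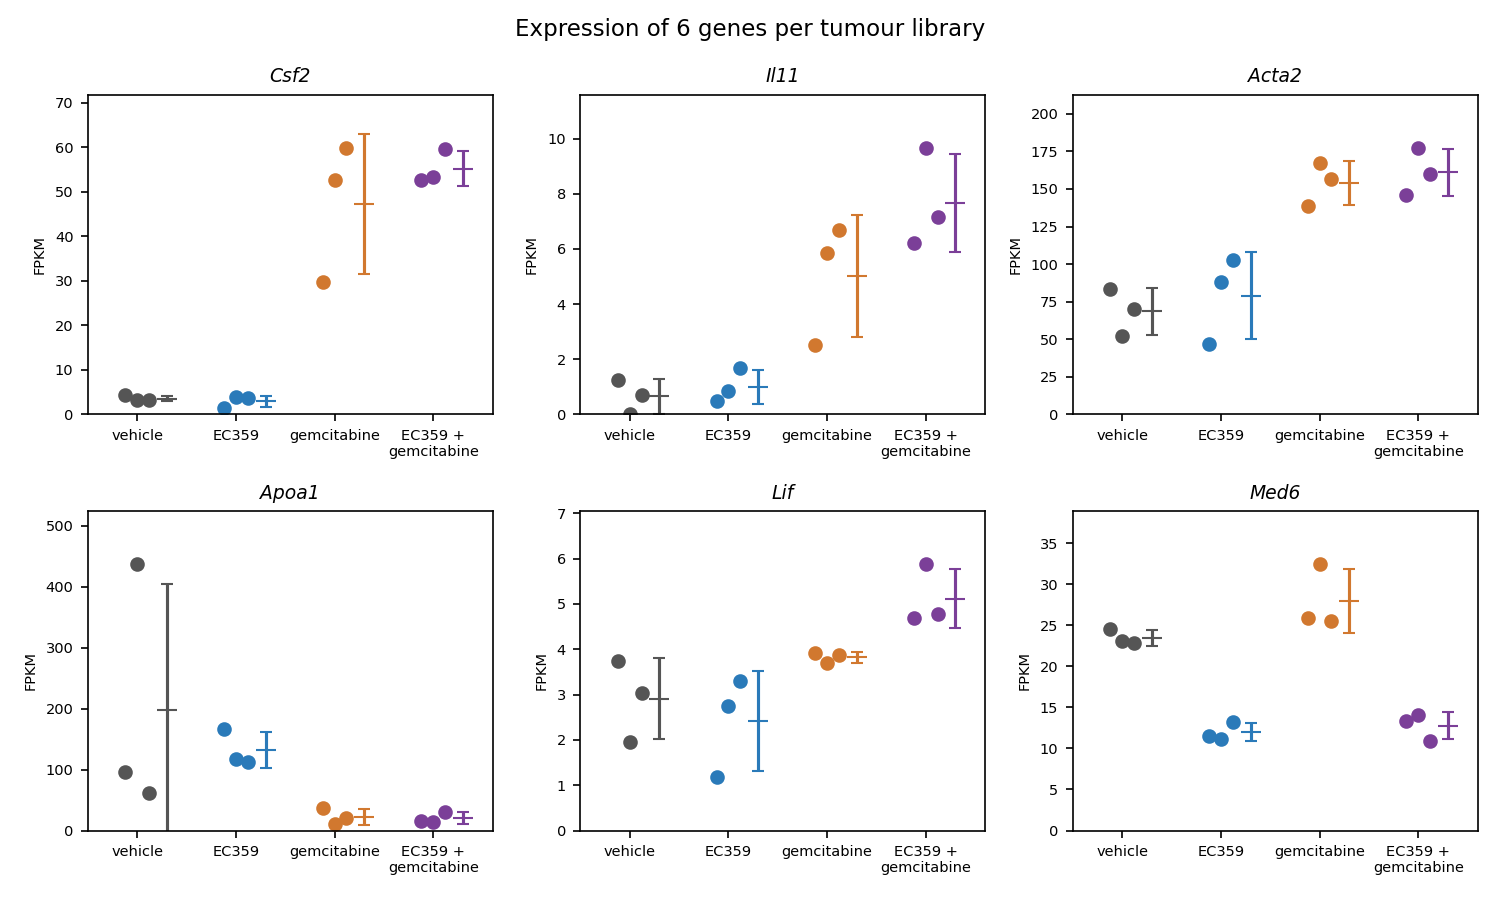
FPKM of 6 genes per library; points are libraries (n = 3 per group), the bar is the mean ± SD, and axes start at 0, so the lower error of Apoa1 with vehicle is not fully drawn. Csf2 was 3.54 ± 0.61 FPKM with vehicle and 47.3 ± 16 with gemcitabine, and Med6 was 10.9 to 14.1 FPKM in the 6 libraries given EC359 and 22.8 to 32.4 in the other 6.

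EC359 was compared with vehicle to ask what LIFR inhibition alone changed. In limma 0 of 12352 genes changed at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 391, where chance alone gives 618, and the smallest adjusted p was 0.176. By unadjusted p, the lowest genes were Med6, a subunit of the Mediator complex (-0.92 ± 0.13; 23.5 ± 0.96 FPKM with vehicle and 12 ± 1.1 with EC359), Cd2bp2 (-1.03 ± 0.16), the transcription factor Ets1 (-1.51 ± 0.30), Nudcd3 (-0.82 ± 0.18) and Ube2q2 (-0.68 ± 0.18). The highest were Rab3d, a GTPase of secretory granules (1.19 ± 0.30), Mob4 (0.83 ± 0.23), the phosphatase Ptp4a1 (0.81 ± 0.19), Cnppd1 (0.64 ± 0.19) and Prkg2 (0.55 ± 0.16). The pathway genes stood at -0.11 ± 0.45 for Lifr, 0.04 ± 0.26 for Il6st, 0.00 ± 0.13 for Stat3 and -0.17 ± 0.18 for Socs3, and Mki67 at -0.02 ± 0.15. Of 18 LIF-IL6 family genes and 22 STAT3 targets, 0 changed by limma, also adjusted over the list alone, and their camera adjusted p was 0.937 and 0.925.

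No member of any list changed with EC359 alone, but camera called 14 lists. Myofibroblastic CAF genes had a median of 0.17 (adjusted p = 7.43e-04; adjusted p = 0.784 with an estimated correlation) and epithelial-mesenchymal transition genes 0.12 (adjusted p = 9.80e-04; adjusted p = 0.758 with an estimated correlation). Acinar genes had a median of -1.75 (adjusted p = 2.91e-06; adjusted p = 0.95 with an estimated correlation), and -0.09 without EC359 library 3. Erythroid genes had a median of 1.07 (adjusted p = 9.25e-04; adjusted p = 0.95 with an estimated correlation), and -0.49 without EC359 library 1. Mitochondrially encoded genes had a median of -0.43 (adjusted p = 8.04e-05; adjusted p = 0.95 with an estimated correlation). Ribosomal protein genes had a median of 0.06 (adjusted p = 9.25e-04, and adjusted p = 0.95 with an estimated correlation). Replication-dependent histones had 0.21 (adjusted p = 0.00256, and adjusted p = 0.95 with an estimated correlation). Both calls were lost without EC359 library 1. Immune lists were lower, with medians of -0.56 for MHC class II (adjusted p = 0.0493), -0.34 for dendritic cell (0.0493), -0.22 for interferon gamma and MHC class I (0.0462) and -0.20 for macrophage genes (0.0214), and mitosis genes had -0.08 (0.0493), each with adjusted p = 0.95 with an estimated correlation. Without EC359 library 2 the adjusted p was 0.862 for MHC class II and 0.788 for interferon gamma, and without EC359 library 1 it was 0.523 for dendritic cell, 0.523 for macrophage and 0.646 for mitosis genes. The last 2 lists were oxidative phosphorylation (median 0.06; adjusted p = 0.0404; adjusted p = 0.95 with an estimated correlation), lost without vehicle 3 or EC359 3, and hypoxia (median 0.12; adjusted p = 0.0493; adjusted p = 0.972 with an estimated correlation), whose median was -0.31 without EC359 1. With acinar and haemoglobin levels this uneven among EC359 libraries, 3 genes changed when libraries 1 and 3 were left out and the lone one was assumed to vary like the other groups. The epithelial-mesenchymal transition call was the 1 of 14 that stood without each library in turn; the myofibroblastic one was lost without vehicle 2 and the mitochondrial one without vehicle 3.

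The combination was compared with gemcitabine to ask what adding EC359 to chemotherapy changed. Med6 (ENSMUSG00000002679.14, GRCm38 chromosome 12, 81573557 to 81595008) was the single gene called by limma, with a fall of -1.07 ± 0.13, from 27.9 ± 3.9 to 12.8 ± 1.7 FPKM (SD, n = 3; adjusted p = 0.0394). Other genes by unadjusted p were higher for Cpne1 (1.58 ± 0.36), Ets1 (1.30 ± 0.30), the pentraxin Ptx3 (1.16 ± 0.26), Timm22 (0.81 ± 0.20) and Arhgap11a (0.56 ± 0.14). Those lower were Pcmtd1 (-1.0 ± 0.30), Clptm1 (-0.79 ± 0.23), the splicing kinase Clk1 (-0.45 ± 0.13) and the respiratory chain gene Ndufa1 (-0.39 ± 0.11). None of these 9 passed (adjusted p = 0.998). Lif stood at 0.34 ± 0.24, Socs3 at 0.10 ± 0.18, Col1a1 at 0.40 ± 0.23, Acta2 at 0.06 ± 0.26 and Mki67 at 0.01 ± 0.15. No list had a changed member. Camera called 13 lists, the highest for MHC class II (median 0.74; adjusted p = 0.0131; adjusted p = 0.763 with an estimated correlation) and dendritic cell genes (median 0.38; adjusted p = 0.0254; adjusted p = 0.763 with an estimated correlation). The lowest were acinar genes (median -0.49; adjusted p = 0.00528; adjusted p = 0.82 with an estimated correlation) and mitochondrially encoded genes (median -0.48; adjusted p = 6.79e-11; adjusted p = 0.563 with an estimated correlation). Ribosomal protein genes had a median of -0.11 (adjusted p = 5.02e-10; adjusted p = 0.682 with an estimated correlation), and that call was lost with quantile normalization (adjusted p = 0.568). The Med6 call was lost without each of the 12 libraries in turn, with adjusted p from 0.0522 to 0.23 (the latter without combination 1), while its log2 fold change stayed between -1.14 and -0.96. The MHC class II and dendritic cell calls were lost without gemcitabine 1 (adjusted p = 0.671 for both) or combination 1 (adjusted p = 0.158 and 0.163), and with Eif2s3y as a covariate (adjusted p = 0.902 and 0.796). The acinar call was lost without combination 2 (adjusted p = 0.373) and with quantile normalization (adjusted p = 0.402) or trimmed means (adjusted p = 0.0782).

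The interaction asks whether EC359 acted differently with gemcitabine than without. In limma 0 genes passed, with 665 at an unadjusted p under 0.05, where chance gives 618, and a smallest adjusted p of 0.388. Ets1 had the smallest p, with an interaction of 2.80 ± 0.42; its mean was 14.8 FPKM with vehicle, 4.55 with EC359, 3.50 with gemcitabine and 11.1 with the combination. Other values were 1.16 ± 0.26 for Nudcd3, 1.13 ± 0.23 for Cd2bp2, 0.87 ± 0.20 for Arhgap11a, 0.66 ± 0.15 for Sipa1, -1.84 ± 0.50 for the NK receptor Klra4, -1.66 ± 0.42 for Rab3d, -0.87 ± 0.27 for Ddt, -0.68 ± 0.17 for the arylamine acetyltransferase Nat2 and -0.48 ± 0.15 for Hddc2. No list member passed over all genes, and camera called 10 lists, none of which had an adjusted p under 0.698 with an estimated correlation. With Eif2s3y as a covariate 4 lists were called.

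The combination was compared with EC359 to ask what adding gemcitabine changed. Csf2 rose by 3.89 ± 0.28 (limma adjusted p = 1.72e-04), followed by Prss3 (3.87 ± 0.77), the antimicrobial lectin Reg3g (3.82 ± 0.90), Ccl24 (3.33 ± 0.35) and Ccl17 (2.66 ± 0.42). Sult1d1 (-3.33 ± 0.65), the membrane protein Emp1 (-2.92 ± 0.62), Apoa1 (-2.71 ± 0.63), Ttr (-2.32 ± 0.38) and Aldh1a1 (-2.25 ± 0.36) fell most. In total 1574 genes changed, 1009 up and 565 down, and 412 at least 2-fold. All 27 mitosis genes rose (27 adjusted over the list alone; median 1.02; camera adjusted p = 4.72e-25; adjusted p = 0.144 with an estimated correlation). All 7 MHC class II genes rose (7 adjusted over the list alone; median 1.90), among them the invariant chain Cd74 (1.90 ± 0.42) and H2-Eb1 (2.10 ± 0.51), with a camera adjusted p of 2.31e-05 (adjusted p = 0.307 with an estimated correlation). Macrophage genes rose in 12 of 20 cases (17 adjusted over the list alone; camera adjusted p = 1.38e-08; adjusted p = 0.307 with an estimated correlation), interferon genes in 14 of 30 (25 adjusted over the list alone; camera adjusted p = 1.38e-08; adjusted p = 0.312 with an estimated correlation) and inflammatory CAF genes in 13 of 18 (15 adjusted over the list alone; camera adjusted p = 2.86e-09; adjusted p = 0.307 with an estimated correlation). Lif (0.90 ± 0.24) and Socs3 (0.69 ± 0.18), a feedback inhibitor induced by STAT3, rose here, with adjusted p of 0.0325 and 0.0286, and Lif was 2.41 ± 1.1 FPKM with EC359 and 5.12 ± 0.65 with the combination (SD, n = 3). Of 18 LIF-IL6 family genes 5 rose, with a camera adjusted p of 0.0298 (adjusted p = 0.401 with an estimated correlation). Of 22 STAT3 targets 5 rose, with a camera adjusted p of 8.40e-04 (adjusted p = 0.307 with an estimated correlation). Ribosomal protein genes had a median of -0.19, and 2 of 36 fell (0 adjusted over the list alone; camera adjusted p = 2.31e-05; adjusted p = 0.469 with an estimated correlation). Acinar genes rose in 5 of 30 cases (6 adjusted over the list alone; median 2.70; camera adjusted p = 7.63e-07; adjusted p = 0.469 with an estimated correlation). Their direction turned without EC359 libraries 1 and 3 (median -0.47), and the call was lost with array weights (median 0.85, camera adjusted p = 0.098). Erythroid genes had a median of -2.04 with 0 of 8 called (camera adjusted p = 0.00751, and adjusted p = 0.477 with an estimated correlation). Their score was 4.14 in EC359 1, 0.05 in EC359 2 and -0.71 in EC359 3. Hypoxia genes had a median of -0.52 with 1 risen and 1 fallen of 23 (camera adjusted p = 0.00403, and adjusted p = 0.533 with an estimated correlation).

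Without EC359 1, combination 1, combination 2 or combination 3, 770, 817, 937 and 617 genes changed in place of 1574, and without EC359 libraries 1 and 3 together 196 did. With the acinar score as a covariate 722 genes changed, where the lost calls kept 94.7% of their median fold change (0.622 to 0.589) and their median SE rose from 0.156 to 0.191; in a fit of the 2 groups alone 899, with array weights 2432, and with Eif2s3y as a covariate 1, which was Csf2. The calls lost with Eif2s3y kept 93.5% of their median fold change, from 0.752 to 0.704, while their median SE rose from 0.163 to 0.243. With that covariate 18 lists were called in place of 22, the mitosis list among them (median 0.96). The score of 4 sex-linked genes was 0.21 to 0.4 with EC359 and -0.55 to -0.31 with the combination. Between these 2 groups, that covariate thus cannot be separated from treatment. The Lif and Socs3 calls were both lost without EC359 1, without combination 2 and without combination 3, and that of Lif also without combination 1.

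The effect of gemcitabine was also compared between mice without and with EC359, in comparisons that share no library. Across genes, Pearson's r of the log2 fold changes was 0.773. By limma 447 genes rose in both where 52.9 were due if calls were independent. Likewise 326 fell in both where 43.2 were due, and 0 changed in opposite directions. The calls used the same fitted spread per gene, so they were not independent and these expected counts are too low. The corresponding effects of EC359 without and with gemcitabine had an r of -0.022. Genes are not independent replicates, so no p is given for either r.

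**Figure D3:**
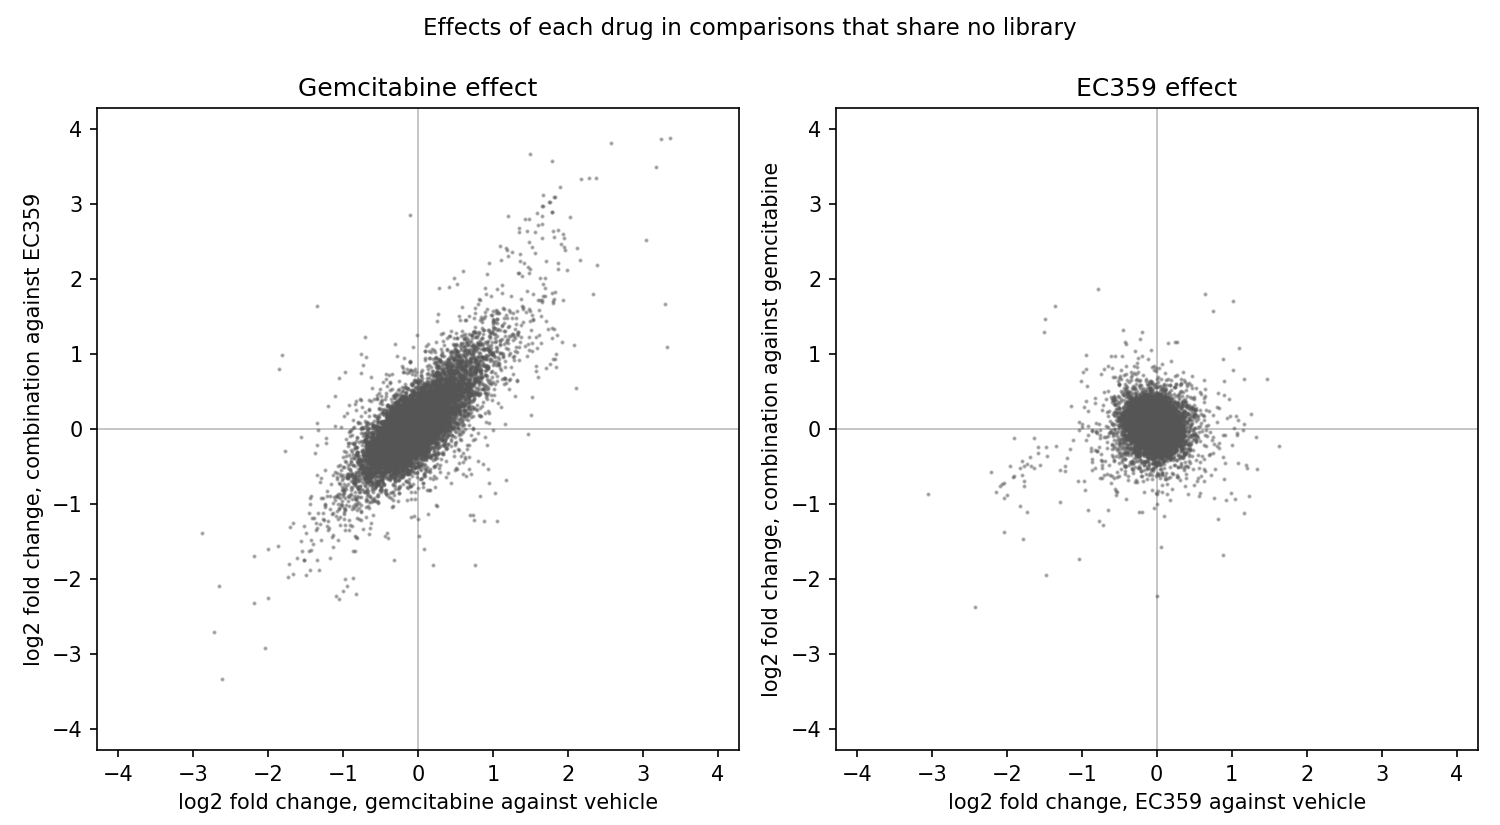
Log2 fold changes of 12352 genes for gemcitabine (left, against vehicle on the horizontal axis and, for the combination, against EC359 on the vertical axis) and for EC359 (right, against vehicle and, for the combination, against gemcitabine); each point is 1 gene. The gemcitabine effects lie along the diagonal with r = 0.773, and the EC359 effects form a round cloud with r = -0.022.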

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

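The pooled comparisons of both arms of each drug, and the tests of the pooled calls against the acinar score, Eif2s3y, a general rise of cycling cells and gene families, were chosen after the results were seen.

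With both arms pooled, 3670 genes changed with gemcitabine, 1823 up and 1847 down, and the share of normal pancreas in each tumour piece could account for part of them. With the acinar score as a covariate, 1931 of the 3670 calls (52.6%) stood. Among the 1739 lost, the median absolute log2 fold change went from 0.385 to 0.341, that is 88.5% of it was kept, while the median SE went from 0.107 to 0.135, so whether these calls come from acinar content cannot be told. With the Y-linked Eif2s3y as a covariate, 2740 (74.7%) stood, and the 930 lost kept 94.7% of their median (0.348 to 0.33; SE 0.109 to 0.123), which argues against its level as the source of the pooled calls. Whether Eif2s3y here follows the host's sex or the implanted cells was not tested. The same cells were implanted in all groups, so they alone would not give such unlike levels unless their share differed between tumours. Eif2s3y is near 0 in the combination, so pairwise calls lost with it do not tell what it stands for from the treatment. Those calls kept 93.5% to 97.6% of the median fold change, with larger SE. The score of 4 measured sex-linked genes was 0.21 to 0.4 with EC359 and -0.55 to -0.31 with the combination, without overlap. With vehicle it was -0.599 in vehicle 2 and 0.214 and 0.27 in the others. With gemcitabine it was -0.405 in gemcitabine 3 and 0.442 and 0.523 in the others. Each library thus lay at -0.311 or lower or at 0.206 or higher. All EC359 libraries were on the higher level and all combination libraries on the lower one. If the score follows sex, sex was not balanced between the groups.

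The rise of mitosis genes in the pooled gemcitabine arms (median 0.884, all 27 risen) could come from acinar content, scaling, transcript length or a larger share of cycling cells. The median was 0.864 with the acinar covariate and 0.862 at the lowest among the scalings, and it lay at percentile 100 of 10000 lists matched for length and level, whose highest median was 0.246, so acinar content, scaling and length or level did not carry it, while other shifts of tissue composition were not tested. Replication genes rose less, with a median of 0.3 (0.388 with the acinar covariate) and 6 of 31 risen. That rise rested mostly on low replication scores in vehicle 2 (-0.421) and EC359 1 (-0.448). The other libraries without gemcitabine stood at -0.085 to 0.071, and those with it at 0.07 to 0.254. The difference of the scores between mitosis and replication was 0.609, with an exact permutation p of 0.005 over 400 arrangements, a test of a contrast already seen. It argues against an equal rise of both lists but not against a larger share of cycling cells, which stays open.

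Med6 fell in the pooled EC359 arms by -1.0 ± 0.09 (limma adjusted p = 0.00242), the 1 gene called there. Its values were 10.9 to 14.1 FPKM in the 6 libraries given EC359 and 22.8 to 32.4 in the others. Neither acinar content nor the level of Eif2s3y accounted for it, with -1.04 under the acinar covariate (adjusted p = 0.00556) and -0.99 under Eif2s3y (adjusted p = 0.0166). As 6 transcripts of 487 to 1059 bp are annotated, a shift between transcripts could lower the FPKM, which these files cannot test. In 36 of 100 splits at least 1 gene changed, with up to 11, so a single call is not rare. The splits only counted calls, so they cannot tell how rare a limma adjusted p of 0.00242 is.

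When the libraries of a pair of groups were exchanged in all 10 ways, the real grouping gave the most calls for gemcitabine against vehicle (1592, highest other 1), the combination against vehicle (1552, highest other 1) and the combination against EC359 (1574, highest other 1), each 1 of 10, and 10 splits are too few for a share under 0.05. For EC359 against vehicle and the interaction the real count is 0, which any split reaches (10 of 10 and 100 of 100), so these counts say nothing of chance. The highest other was 11 for the interaction and 257 for EC359 against vehicle. The split with 257 set vehicle 1, vehicle 3 and EC359 3 against vehicle 2, EC359 1 and EC359 2. They lay apart on the second principal component (15.2% of the variance), at 6.6 to 29.9 and at -27.5 to -8. The labels do not name what this structure is. For the combination against gemcitabine 6 of 10 splits gave at least 1 call (highest other 5). The pooled gemcitabine count of 3670 was reached in 1 of 100 (highest other 3). The correlation of the EC359 effect without and with gemcitabine was -0.022, reached in 63 of 100 splits (highest other 0.215), against 0.773 for gemcitabine, reached in 1 of 100 (highest other 0.663).

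By camera, 10 lists differed in the effect of EC359 with gemcitabine minus without. Median differences were 0.177 for mitosis, 0.397 for type I interferon, 0.431 for interferon gamma and MHC class I, 1.415 for MHC class II, 0.5 for macrophage and 0.717 for dendritic cell genes. They were -0.106 for epithelial-mesenchymal transition, -0.074 for oxidative phosphorylation, -1.085 for erythroid and -0.175 for ribosomal protein genes. With an estimated correlation the adjusted p = 0.806 for type I interferon and 0.698 for each of the others, and 0 single genes passed. With Eif2s3y as a covariate 8 of these 10 calls were lost, those of oxidative phosphorylation and ribosomal protein genes not, and the MHC class II difference went to 0.25 (adjusted p = 0.93), so what Eif2s3y follows may account for it in part or whole, and the near absence of that gene in the combination keeps this from being separated from treatment. It was 0.956 without EC359 2 (adjusted p = 0.0648) and 0.896 without gemcitabine 1 (adjusted p = 0.138), and the erythroid one was 0.413 without EC359 1.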

How the results depend on the processing

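The alternatives were fixed before the files were opened, except the covariates, the removal of the acinar list, the removal of EC359 libraries 1 and 3, and the pooled comparisons, which were added after seeing the data.

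EC359 against vehicle gave 0 genes in every planned setting but 1 without combination 3, and 1 with the acinar covariate and 3 without EC359 libraries 1 and 3. Gemcitabine against vehicle (1592) gave 111 to 2132 with a library left out, with 274 without vehicle 1, 661 without vehicle 2, 165 without gemcitabine 2 and 111 without gemcitabine 3. It gave 3518 with array weights, 848 with only the 2 groups, 1050 with replicate number as a block, 790 with the acinar covariate and 693 with Eif2s3y. The combination against vehicle (1552) gave 632 to 1906 with a library left out: 720 without vehicle 1, 858 without vehicle 2, 728 without combination 1, 953 without combination 2 and 632 without combination 3. It gave 2427 with array weights and 598 with Eif2s3y.

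The combination against EC359 (1574) gave 617 to 1681: 770 without EC359 1, 817 without combination 1, 937 without combination 2 and 617 without combination 3. It gave 2432 with array weights, 899 with only the 2 groups, 722 with the acinar covariate, 1 with Eif2s3y and 196 without EC359 libraries 1 and 3. The combination against gemcitabine (1) gave 0 to 3, with 0 without any vehicle or EC359 library, gemcitabine 3, combination 1 or combination 2, 3 without combination 3, and 1 without gemcitabine 1 or 2; none of the latter calls was Med6. It gave 0 when rescaled to a sum of 1000000, with only the 2 groups, with the block, with either covariate, with the acinar list removed, and without EC359 libraries 1 and 3. The interaction (0) gave 1 without gemcitabine 3, 2 without combination 3 and 1 without EC359 libraries 1 and 3. The pooled gemcitabine count (3670) ran from 2641 to 3791 and was 2095 with the acinar covariate. The pooled EC359 count (1) was 2 without gemcitabine 1, 3 without combination 3 and 2 without EC359 libraries 1 and 3.

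Scaling moved the median over all genes, and quantile normalization also moved lists relative to it. Rescaling moved the median log2 fold change of gemcitabine against vehicle from -0.055 to -0.181 and the share of its calls that rose from 40.7% to 22.6% (1972 genes), against 49.6% with trimmed means, 49.7% with the acinar covariate and 58.0% with Eif2s3y. For the combination against EC359 that share went from 64.1% to 50.2% with trimmed means (1805 genes) and 49.4% with quantiles (1595). In the pooled gemcitabine arms it went from 49.7% to 39.1% when rescaled (3730). The median interaction went from 0.099 to -0.002 with trimmed means, 0 with quantiles and 0.215 when rescaled, and the combination against gemcitabine from 0.053 to 0.137 when rescaled.

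Lists called by camera were 14 for EC359 against vehicle (10 to 14 with a library left out), 16 for gemcitabine against vehicle (13 to 20), 23 for the combination against vehicle (20 to 24), 13 against gemcitabine (3 to 17), 22 against EC359 (18 to 24) and 10 for the interaction (5 to 16). With an estimated correlation each of the 6 was 0. For EC359 against vehicle there were 9 with array weights, 8 with Eif2s3y and 9 with the acinar list removed. For the combination against gemcitabine there were 8 with a pseudocount of 0.1, 7 with the filter at 2 FPKM, 8 with quantiles, 4 with array weights, 3 with Eif2s3y, 5 without gemcitabine 1 and 3 without combination 1. For the interaction there were 4 with Eif2s3y, 16 without EC359 1 and 5 without gemcitabine 1. Fry called the mitosis list for gemcitabine against vehicle (adjusted p = 2.81e-04) and for the combination against vehicle (9.89e-05) and against EC359 (4.25e-05). It also called myofibroblastic (0.00391) and inflammatory CAF (0.00505), epithelial-mesenchymal transition (0.00505) and matrix genes (0.0454) for gemcitabine against vehicle. Genes of gemcitabine metabolism (0.0265) and intestine (0.0289) were called there as lower. Fry called further lists for the combination against vehicle and against EC359. They included myofibroblastic (0.00125 and 0.00421) and inflammatory CAF genes (0.00217 and 0.00197). STAT3 targets (0.00865 and 0.00563) and LIF-IL6 family genes (0.0462 and 0.017) were also among them. The lowest fry adjusted p was 0.886 for EC359 against vehicle, 0.644 for the combination against gemcitabine and 0.646 for the interaction. Fry does not set a list apart from other changed genes.

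The test direction of a called list turned in 24 cases, none of them under a scaling. Lists not called in the main fit were not counted. For EC359 against vehicle the medians were then -0.03 (mitosis, array weights) and 0 (mitosis, without EC359 1 and 3); -0.093, -0.314 and -0.344 (hypoxia; array weights, without EC359 1, without EC359 1 and 3). Acinar genes stood at 0.177 with array weights, -0.094 without EC359 3, -0.053 with the acinar covariate and 1.322 without EC359 1 and 3, macrophage genes at -0.027 with Eif2s3y, erythroid genes at -0.494 without EC359 1 and 0.025 without 1 and 3, and ribosomal protein genes at -0.044 with array weights, -0.004 without EC359 1 and -0.115 without 1 and 3. Acinar genes with the acinar covariate stood at -0.11 for the combination against vehicle and -0.134 against EC359, and at -0.472 against EC359 without EC359 1 and 3. The acinar covariate is the mean of these same genes, so their values near 0 under it, the -0.053 included, follow from the fit. Against gemcitabine, type I interferon genes stood at 0.047 without combination 1, and with Eif2s3y interferon gamma genes stood at 0.005, MHC class II at 0.045 and acinar genes at 0.204. In the interaction macrophage genes stood at -0.064 with Eif2s3y and erythroid genes at 0.413 without EC359 1. The cause was not tested for any of the other cases. With the other libraries left out, the same lists ranged up to 0.351 (hypoxia, without EC359 3), -3.327 (acinar, without EC359 2), 2.066 (erythroid, without EC359 3) and 0.154 (ribosomal, without EC359 2) for EC359 against vehicle, 0.274 (type I interferon, without combination 3) against gemcitabine, and -2.103 (erythroid, without EC359 3) in the interaction. No named gene that was called in the main fit turned direction, and changes of sign among genes not called were not counted.

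Of the called lists, 1 of 14, 11 of 16, 14 of 23, 2 of 13, 15 of 22 and 2 of 10 stood without each library, in the order above. Without vehicle 1 the LIF-IL6 family call of the combination against vehicle was lost (adjusted p = 0.0603). Replicate numbers did not pair the libraries: across 18 pairs of the same number r ran from -0.304 to 0.206 (median -0.0475, against 0.013 for 36 pairs of different numbers), and the block gave 1050, 1260 and 1217 genes for gemcitabine and the combination against vehicle and the combination against EC359.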

Other observations

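The comparison of gene families and the search for genes on separate levels were chosen after the results were seen.

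Many, but not all, genes of drug and retinoid metabolism were lower with gemcitabine. Of 99 measured genes in 8 families, 48 fell (48.5%), 12 rose and 39 did not pass in the pooled gemcitabine arms, where 14.7% of the 12253 other genes fell (1799). The families were picked because some of their members, such as Sult1d1 and Aldh1a1, were among the largest falls, so that difference is a description and no p is given. The falls took in 11 of 24 cytochrome P450 genes (Cyp), 11 of 23 glutathione transferases (Gst), 8 of 18 aldehyde dehydrogenases (Aldh; 4 rose, median -0.04), 6 of 13 glucuronosyltransferases (Ugt), 5 of 11 aldo-keto reductases (Akr), 3 of 5 sulfotransferases (Sult), 2 of 3 alcohol dehydrogenases (Adh) and 2 of 2 epoxide hydrolases (Ephx). Against vehicle 31 of the 99 fell and 6 rose with gemcitabine, and 36 fell and 7 rose with the combination. With the other scalings the pooled share was 49.5% to 52.5% against 16.8% to 18.1% of other genes. Why they fell was not tested.

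Of 4 measured mesothelial genes, 2 fell and 2 were higher without passing. Msln, which encodes mesothelin, fell by -0.78 ± 0.19 with gemcitabine and -0.89 ± 0.19 with the combination, and Nkain4 by -1.43 ± 0.25 and -1.79 ± 0.25. Upk1b stood at 0.44 ± 0.31 and 0.71 ± 0.31, and Wt1 at 0.47 ± 0.18 and 0.6 ± 0.18. With 4 genes the list was not tested.

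Among 6881 genes with a mean of at least 5 FPKM, 36 had 12 values that fell on 2 levels with an empty gap of at least 0.8 log2. Gemcitabine split 5 of them, EC359 split 0, and 31 followed neither exactly, such as Gpx1 with a gap of 2.11 and Ets1 with 1.29. Emp1, with 2.49, was low in all 6 libraries given gemcitabine and in vehicle 2. Reads assigned to transcripts of different length could produce such levels, but 80.6% of these genes had annotated transcripts differing at least 2-fold in length, and the mean of matched genes was 80.6% (permutation p = 0.6), so that reason has no support here. For Ets1, calls between groups of 3 may thus depend on which libraries fell on which level.

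The effects of gemcitabine and of the combination against vehicle share the vehicle libraries. Their r was 0.887 where simulated data with no effect gave 0.5, and their covariance was 0.1704 against 0.0242. For EC359 and gemcitabine, which also share vehicle, r was 0.107 against 0.502, and the covariance 0.0105 against 0.0242. At the simulated spread the shared vehicle could thus by itself produce more similarity than was seen. That spread was fitted over all 4 groups, not the vehicle libraries alone, and the simulated noise was independent between genes.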
